A study of Homo sapiens with 7 samples.

How the data were processed

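RNA of 7 SKOV3 samples was hybridised to Affymetrix Human Gene 1.1 ST arrays, which measure whole transcripts through many probes per transcript cluster. Per the labels, clones were made by lentiviral infection and kept under puromycin. The labels' extraction protocol names a silica column kit, while the design text names TRIzol, so the method of extraction is not settled. The cell line field gives SKOV3 for every sample, while the 7 source names differ from each other. The authors' deposited values are log2 signals, 1 per transcript cluster and array, made with Affymetrix Expression Console and RMA per the submitters' processing notes, which give no version. RMA corrects the background, makes the distributions of the probe signals equal across arrays and then summarises probes by median polish. The medians of the deposited columns were not equal, which summarising after that step allows. The values do not show whether a further step was applied. The genome build was not given in the sources used here, and no coordinates are printed. Groups and replicate numbers were taken from the sample titles.

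The table holds 33297 transcript clusters. GEO's platform annotation gives exactly 1 gene symbol for 19181 of them and several for 2055, and does not list 12061. Only clusters with 1 symbol were named. Symbols were updated through Entrez identifiers with the RefSeq genes of GRCh38.p14 for 17930 genes, and 28 kept the annotation's symbol. Where a gene had several clusters (895 genes), the one with the highest mean over the 7 arrays was used, which left 17958 genes. No dim cluster was filtered out. Array data give no read depth, so the precision rests on the number of arrays.

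An array-wise linear model with 3 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit and default eBayes) on all 7 arrays, so that the groups shared 1 estimate of the spread with 4 residual degrees of freedom. The 3 comparisons were the arrays labelled CtBP1 knockdown against scramble control, CtBP2 knockdown against scramble control, and the knockdowns against each other. P-values are two-sided and were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. Errors after ± are standard errors of the fit unless named otherwise. Figures were drawn with matplotlib 3.10.9.

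The tests, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where said. The 29 lists hold 790 different genes, 718 of them measured, and were written from textbook knowledge of DNA repair, the cell cycle, cell death, CtBP function, cell identity, signalling, stress and metabolism. Each was tested with camera at a preset inter-gene correlation of 0.01 and with an estimated correlation, adjusted over the lists within a comparison. A gene can belong to several lists. Named genes were, per comparison and direction, up to 10 genes past the threshold with separated groups, filled up to 10 by the smallest unadjusted p among genes with separated groups. Placeholder, LOC, LINC, MIR and SNOR symbols and Y-linked genes were passed over. CTBP1, CTBP2 and up to 4 members with the smallest p of each list described were named too.

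Simulated data on the real means and a pooled spread were used to check the fit. Of 50 genes changed by 1 log2 unit, 32% were recovered for the arrays labelled CtBP1 knockdown against scramble, 18% for CtBP2 knockdown against scramble and 40% for the direct comparison. At 2 log2 units the shares were 88%, 82% and 94%. False calls numbered 12, 6 and 10 among 17958 genes. With each group's own spread in the simulation, in which the scramble arrays vary most, false calls numbered 375, 193 and 10. Camera called 0 lists in simulated data without change and found a list shifted by 0.5 in each comparison. The simulated genes were independent of each other, while the correlations estimated for the called lists reached 0.818, so this does not check the calls of lists whose genes vary together.

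Of the genes tested, 7180 (40%) had an identical value on 2 or more arrays. Such ties occurred between every pair of arrays, for 455 to 1082 genes a pair. On both CtBP2 knockdown arrays 972 genes were tied, and CTBP1 was tied on arrays 2 and 3 labelled CtBP1 knockdown. Ties within a group can understate a gene's spread, while ties between groups do not enter it. A fit without any of the tied genes was added after the ties were seen. The other alternatives were renewed quantile normalization, median centring, filters on dim genes, other rules for several clusters, a mean-variance trend, robust eBayes, fits on only the groups compared, array weights, the replicate number as a block, and leaving out each array. Where an array is left out and its group keeps a lone array, that array is assumed to vary like the other groups.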

Results

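Gene expression was measured in SKOV3, a human ovarian carcinoma cell line, in stable lentiviral clones meant to lack either CtBP1 or CtBP2. These related proteins are transcriptional co-repressors that bring histone-modifying enzymes to promoters. The series holds 7 Affymetrix Human Gene 1.1 ST arrays, which are 2 of scramble control clones, 3 labelled CtBP1 knockdown and 2 labelled CtBP2 knockdown. The deposited log2 signals ran from 0.60 to 12.54, and 17958 genes were tested. The number of arrays limits the precision. The labels call the samples clones, and nothing says whether cultures were grown apart, so the p-values measure only the spread between these arrays, which may be technical.

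Scramble control 1 stood apart from every other array. Over all tested genes it correlated with the other arrays at 0.926 to 0.941, while the other 6 arrays correlated with each other at 0.971 to 0.993. Genes are not independent replicates, so these values describe the arrays. Its interquartile range was 2.20 log2 units against 2.85 to 3.15 elsewhere. For genes at mean levels of 0.955 to 2.08 on the other 6 arrays, scramble control 1 differed from that mean by a median of 0.212. For genes at 5.13 to 11.6 it differed by -0.654. It also held the lowest signals of dividing-cell genes: the median over the G2/M and mitosis list, relative to each gene's mean over the 7 arrays, was -1.56 on scramble control 1 and 0.50 on scramble control 2. The CtBP2 knockdown arrays were the closest pair (r = 0.993), and their median absolute difference of 0.117 shows that they are not a single array deposited again.

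**Figure D1:**
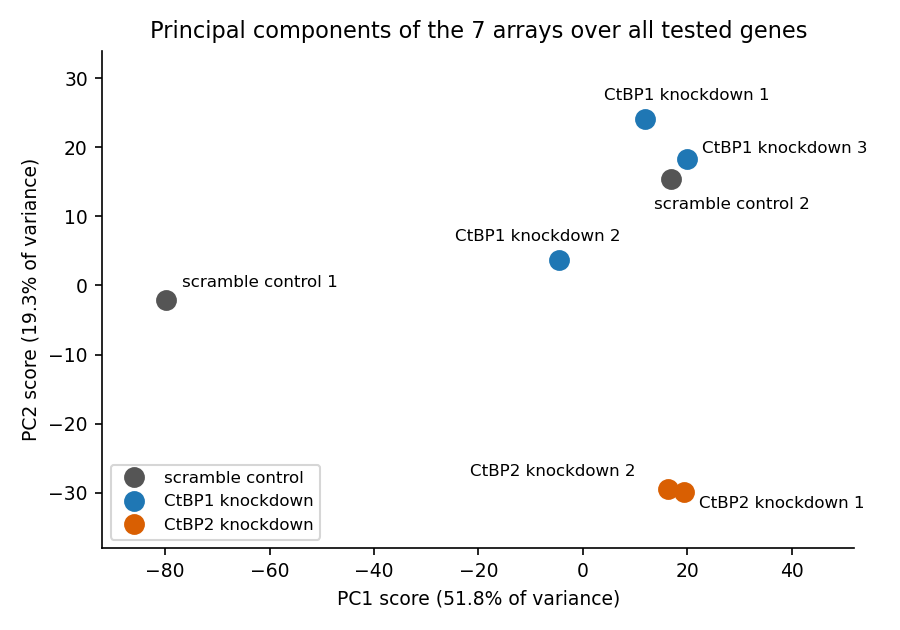
Scores of the 7 arrays on the principal components PC1 (51.8% of the variance) and PC2 (19.3%) over all tested genes, 1 point per array, coloured by group. Scramble control 1 lies alone at -79.9 on PC1, and the CtBP2 knockdown arrays lie together at the low end of PC2.

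CTBP2, the gene targeted in the CtBP2 knockdown, had log2 signals of 4.64 and 4.22 on the CtBP2 knockdown arrays, against 5.70 and 6.14 on the scramble arrays and 6.25, 6.31 and 6.27 on the arrays labelled CtBP1 knockdown. Its log2 difference from scramble was -1.49 ± 0.21 (SE of the limma fit), a 2.81-fold lower signal with no overlap between the groups, at an adjusted p of 0.18. The adjusted p was 0.0177 without scramble control 2, which leaves the outlying scramble control 1 as the lone control, and the difference was then -1.27. It was 0.187 without scramble control 1, and 0.93 and 0.69 without CtBP2 knockdown arrays 1 and 2, and lay between 0.0177 and 0.93 under all alternatives tried. A dimmer CTBP2 transcript cluster differed by -0.07, and the mean of both clusters by -0.78. CTBP1 gave another picture. Its signals were 5.11, 6.13 and 6.13 on the arrays labelled CtBP1 knockdown, and 5.69 and 6.37 on the scramble arrays, so 2 of the 3 labelled arrays, with identical values, lay between the controls. The log2 difference was -0.25 ± 0.39 (SE) with an adjusted p of 0.849. It was -0.59 without scramble control 1 and turned to 0.09 without scramble control 2 or without CtBP1 knockdown array 1. The labels report that knockdown was checked by western blot, which measures protein. Since the CTBP1 signal does not separate these arrays from the controls, they are called the arrays labelled CtBP1 knockdown throughout.

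**Figure D2:**
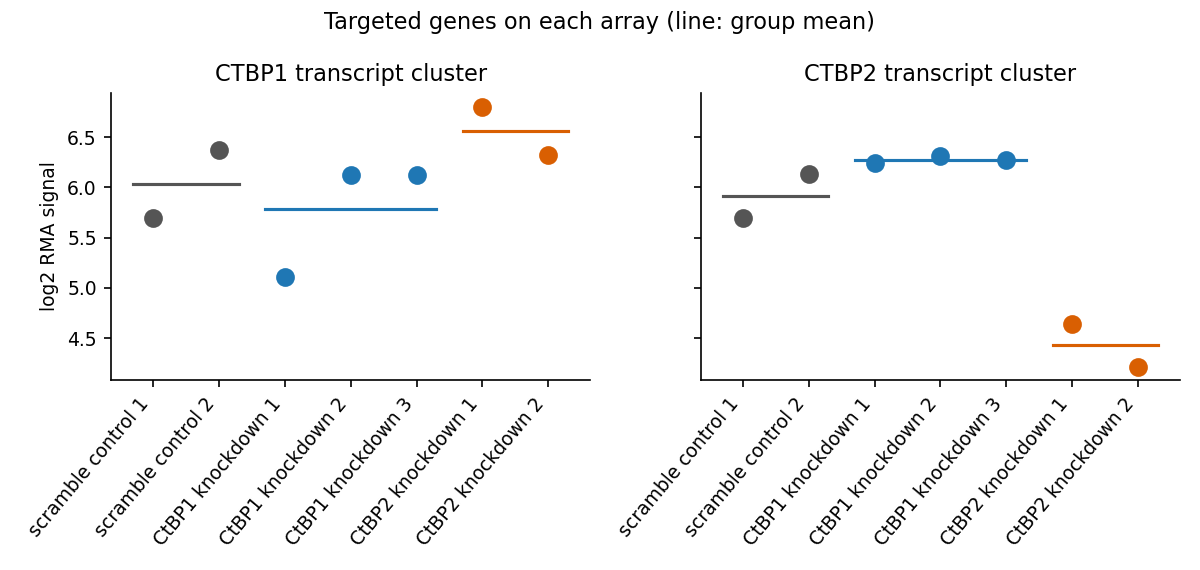
Log2 signal of the brightest CTBP1 cluster (left) and CTBP2 cluster (right) on each of the 7 arrays, 1 point per array, with a line at each group's mean. CTBP2 lies at 4.64 and 4.22 on the CtBP2 knockdown arrays, below all others, while CTBP1 lies at 6.13 on 2 of the arrays labelled CtBP1 knockdown, between the controls at 5.69 and 6.37.

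The arrays labelled CtBP1 knockdown were compared with scramble control to ask which genes depend on CtBP1. Higher on these arrays than on both controls was ADGRG1, an adhesion G protein-coupled receptor, by 2.61 ± 0.33 on the log2 scale (SE, 3 arrays against 2), or 6.12-fold. LRRN4, which encodes a leucine-rich repeat membrane protein, differed by 2.52 ± 0.29. IL1R1, the signalling receptor for interleukin-1, differed by 1.68 ± 0.26, and EPAS1, a hypoxia-inducible transcription factor, by 1.75 ± 0.25. On the lower side, CACNA2D1, an auxiliary subunit of voltage-gated calcium channels, differed by -1.96 ± 0.26 and ZFPM2, a cofactor of GATA transcription factors, by -1.24 ± 0.16. None of these differences passed the test: limma called 0 of 17958 genes at an adjusted p under 0.05, the smallest adjusted p was 0.734, and 861 genes (516 higher, 345 lower) had an unadjusted p under 0.05. That last count was 1379 without scramble control 1, 6516 without scramble control 2, 496 without CtBP1 knockdown array 3 and 538 without either CtBP2 knockdown array.

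The other genes chosen by the same rule, none of them past the threshold, were on the higher side TMEM92 (1.09 ± 0.13), the tetraspanin TSPAN1 (1.21 ± 0.17), AFAP1L2 (1.42 ± 0.22), the integrin subunit ITGB3 (1.11 ± 0.18), TPD52L1 (1.12 ± 0.18) and PFKFB3 (0.85 ± 0.14), which makes an activator of glycolysis. On the lower side they were the origin recognition subunit ORC5 (-0.92 ± 0.14), PROS1, which encodes the anticoagulant protein S (-0.90 ± 0.14), the bicarbonate cotransporter SLC4A4 (-0.77 ± 0.13), LIN7C (-0.66 ± 0.12), the signal recognition particle protein SRP54 (-0.69 ± 0.13), CHPT1 (-0.93 ± 0.17), the tRNA methyltransferase TRMT13 (-0.72 ± 0.13) and TMEM260 (-0.96 ± 0.18). In all of them every array of one group lay above every array of the other. Over all genes, 2577 (14.4%) had such separated groups, where chance gives 20%. Without scramble control 2, 3262 genes passed the threshold, in a fit that leaves scramble control 1 as the lone control and takes its spread from the other groups. Without any other single array none did.

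Camera with a preset correlation called 6 of the 29 gene lists for the arrays labelled CtBP1 knockdown, 4 higher and 2 lower. The hypoxia response list was lower at a median log2 difference of -0.36 (adjusted p = 2.34e-04), with 17 of 18 measured genes below scramble. With an estimated correlation the call was lost (adjusted p = 0.702). Its members with the smallest p were STC2 (-0.42 ± 0.13), NDRG1 (-1.40 ± 0.44), KDM3A (-0.53 ± 0.18) and CA12 (-1.05 ± 0.44). The unfolded protein response list was lower at -0.33 (adjusted p = 4.03e-04), with 22 of 30 genes below scramble, and was not called with an estimated correlation (adjusted p = 0.308). Its leading members were DDIT4 (-0.82 ± 0.16), PHGDH (-1.60 ± 0.46), DDIT3 (-1.61 ± 0.47) and ASNS (-1.26 ± 0.37). PHGDH and ASNS are enzymes of serine and asparagine synthesis, and DDIT3 is a stress-induced transcription factor. No member of either list passed on its own, over all genes or adjusted over the list alone. Between the controls (scramble control 1 minus 2) the hypoxia and unfolded protein response lists differed by 0.11 and 0.04. Both lay above random lists matched on mean level (percentiles 99.97 and 100), so the controls disagreed on these lists. With the preset correlation these 2 lists were called in the same direction without each array in turn. The size of single members followed the control kept: without scramble control 1 and without scramble control 2, DDIT3 differed by -0.74 and -2.48, ASNS by -0.59 and -1.94, NDRG1 by -0.60 and -2.19, and CA12 by -0.57 and -1.52.

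The 4 lists called higher were those of dividing cells, whose medians were lowest on scramble control 1. Between the controls the replication-dependent histone list differed by -0.43 (scramble control 1 minus 2). That was like random lists matched on mean level (percentile 39.6). The G2/M and mitosis list had a median of 0.76 (adjusted p = 1.46e-07, or adjusted p = 0.759 with an estimated correlation), with 45 of 47 genes higher. Its leading members were MAD2L1 (0.74 ± 0.28), AURKB (0.97 ± 0.39), MYBL2 (1.22 ± 0.58) and ESPL1 (0.94 ± 0.45), and no member passed when adjusted over the list alone. Without scramble control 1 the list was called lower, at -0.25 (adjusted p = 1.27e-04), and without scramble control 2 its median was 1.68. The DNA replication list had a median of 0.34 (adjusted p = 1.97e-04, or adjusted p = 0.759 with an estimated correlation) with 41 of 47 genes higher, among them CDT1 (0.58 ± 0.19), MCM5 (0.85 ± 0.35) and ASF1B (1.25 ± 0.57). ORC5 went the other way and was the list's 1 member past the threshold adjusted over the list alone. It did not pass without scramble control 1 (adjusted p = 0.0766) or without CtBP1 knockdown array 1, 2 or 3 (adjusted p = 0.127, 0.115 and 0.113). Without scramble control 1 the DNA replication median was -0.09 (adjusted p = 0.106), without scramble control 2 it was 0.91, and without CtBP1 knockdown array 3 it was 0.23. The homologous recombination list had a median of 0.27 (adjusted p = 0.00537, or adjusted p = 0.759 with an estimated correlation), led by DNA2 (1.22 ± 0.42), SEM1 (0.87 ± 0.34), RAD51D (0.31 ± 0.14) and SLX4 (0.45 ± 0.22), and was -0.15 (adjusted p = 0.249) without scramble control 1 and 0.53 without scramble control 2. The replication-dependent histone list had a median of 0.26 (adjusted p = 0.0297, or adjusted p = 0.759 with an estimated correlation), led by H1-5 (0.95 ± 0.31), H1-4 (0.63 ± 0.26), H4C3 (-0.57 ± 0.26) and H3C2 (0.94 ± 0.46). No member of these 2 lists passed when adjusted over the list alone. The histone list lost its call without scramble control 1 (median 0.09, adjusted p = 0.369) or CtBP1 knockdown array 3 (median 0.17, adjusted p = 0.349). Its median was 0.52 without scramble control 2 and 0.40 without CtBP1 knockdown array 1. Over the 6 called lists, 17 of the 24 leading members moved by over 1.5 times without a scramble array, and 0 changed sign. They were chosen by the smallest p on these same arrays, which makes a change of sign unlikely. The direction of 3 of the 6 lists did turn without scramble control 1. The 23 lists not called had medians from -0.09 to 0.29 and adjusted p from 0.0702 to 0.959. Without scramble control 2, 13 lists were called. Of the 23, 11 were called without 1 array. Without scramble control 1 these were the inflammatory (0.33), immediate-early (0.10) and cholesterol (-1.10) lists. Those called without scramble control 2 were excision and mismatch repair (0.43), Fanconi anaemia (0.47), mitochondrial complexes (0.46), glycolysis (0.33), cholesterol (1.00), fibroblast and endothelial markers (-0.18) and leukocyte markers (-0.25). Without CtBP1 knockdown array 1 they were the ribosomal (0.23), mitochondrial (0.29) and inflammatory (0.21) lists, without array 2 the ERBB2 amplicon (0.34) and fibroblast (-0.14) lists, and without array 3 the inflammatory list (0.11). With an estimated correlation none of these was called, at adjusted p from 0.363 to 0.878.

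The comparison of CtBP2 knockdown with scramble control asks which genes depend on CtBP2. RNU4-1, a U4 small nuclear RNA of the spliceosome, rose by 3.85 ± 0.23 on the log2 scale (SE, 2 arrays against 2), or 14.4-fold, and was the only gene past the threshold (limma, adjusted p = 0.0491). TGFBI, a matrix protein induced by TGF-beta, differed by 4.14 ± 0.43, IL1R1 by 3.17 ± 0.28, NT5E, the cell-surface enzyme that makes adenosine from AMP, by 1.85 ± 0.16, and NFKB1, which encodes an NF-kB subunit, by 1.34 ± 0.13. On the lower side were ZFPM2 (-1.34 ± 0.17), the Krüppel-like factor KLF7 (-1.22 ± 0.16) and CTBP2 itself. These others did not pass, with adjusted p from 0.153 to 0.18.

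Further genes named by the rule without passing it were RNASET2 (1.20 ± 0.12), the cyclin CCNQ (1.52 ± 0.15), the immunoproteasome subunit PSMB9 (1.41 ± 0.14), PFKFB3 (1.43 ± 0.16) and the metallothionein MT1G (1.21 ± 0.14) on the higher side. On the lower side were PROS1 (-1.05 ± 0.15), LIN7C (-0.88 ± 0.13), GDPD3 (-0.79 ± 0.12), CTDSPL2 (-1.05 ± 0.17), the G protein subunit GNG11 (-0.71 ± 0.12), EFCAB7 (-0.82 ± 0.14) and SLC4A4 (-0.78 ± 0.14). The test called 1 gene higher and 0 lower, and 1827 genes (1291 higher, 536 lower) had an unadjusted p under 0.05. The latter count was 7124 without scramble control 2, and 778 and 923 without CtBP2 knockdown arrays 1 and 2. Separated groups were seen for 7355 genes (41.0%), where chance gives 33.3%. The RNU4-1 call is uncertain. The 13 small nuclear RNA genes measured, RNU4-1 among them, had a median difference of 1.15 from scramble, with 9 higher and 0 lower on both CtBP2 knockdown arrays than on both controls, and the labels and the design text name different RNA extraction methods. A near-identical gene copy exists, and the call was lost without scramble control 1 (adjusted p = 0.18), without each of CtBP1 knockdown arrays 1, 2 and 3 (adjusted p = 0.231, 0.133 and 0.15), and without CtBP2 knockdown array 1 or 2 (adjusted p = 0.832 and 0.605). Without scramble control 2, 3952 genes passed, again with scramble control 1 as the lone control.

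Camera called 13 lists for the CtBP2 knockdown, 12 higher and 1 lower, and none with an estimated correlation. Genes of the cytosolic ribosome had a median log2 difference of 0.78 (adjusted p = 6.93e-15, or adjusted p = 0.545 with an estimated correlation), with 43 of 45 genes higher. RPL11 (1.96 ± 0.24) and RPS10 (1.18 ± 0.17) rose when adjusted over the list alone, and RPS27 (1.32 ± 0.32) and RPS20 (1.33 ± 0.32) followed without passing. RPL11 and RPS10 did not pass without CtBP2 knockdown array 1 (adjusted p = 0.0514 and 0.124) or 2 (adjusted p = 0.0751 for both). The replication-dependent histone list had a median of 0.69 (adjusted p = 2.55e-07, or adjusted p = 0.545 with an estimated correlation), and 7 of its 22 members rose when adjusted over the list alone. It was led by H2BC8 (1.40 ± 0.22), H4C1 (0.95 ± 0.17), H2AC6 (1.37 ± 0.26) and H2AC4 (1.74 ± 0.34). Of those 7, 3 passed without scramble control 1, and 4 and 0 without CtBP2 knockdown arrays 1 and 2. The DNA replication list had a median of 0.68 (adjusted p = 1.89e-10, or adjusted p = 0.545 with an estimated correlation), with 44 of 47 genes higher and none past the list threshold, led by GINS2 (0.70 ± 0.17), RFC2 (1.29 ± 0.35), MCM2 (1.02 ± 0.28) and MCM6 (0.93 ± 0.26). With the preset correlation these 3 lists were called without each array in turn, with medians of 0.62, 0.56 and 0.22 without scramble control 1. The DNA replication median was 1.28 without scramble control 2. Between the controls (scramble control 1 minus 2) the ribosomal list differed by -0.14, above random lists matched on mean level (percentile 100). The DNA replication list differed by -1.12, below them (percentile 0.03), and the histone list differed like them (percentile 39.6). Ribosomal protein and histone genes have near-identical copies, so a value may mix several genes.

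The calls of 5 lists of growth and metabolism depended on single arrays, and of their members only PFKFB3 passed when adjusted over the list alone, as it did without each array in turn. Between the controls the mitochondrial, glycolysis and Fanconi anaemia lists differed like random lists matched on mean level (percentiles 65.3, 26.5 and 13.2). The G2/M and homologous recombination lists lay below such random lists (percentiles 0 and 0.97). The G2/M and mitosis list had a median of 1.08 (adjusted p = 5.74e-09, or adjusted p = 0.545 with an estimated correlation), with 46 of 47 genes higher, led by CKS2 (1.11 ± 0.21), BUB3 (1.01 ± 0.25), MAD2L1 (1.23 ± 0.31) and CDC25A (1.31 ± 0.37). Its median was -0.07 (adjusted p = 0.85) without scramble control 1 and 1.97 without scramble control 2. The mitochondrial respiratory complex list had a median of 0.48 (adjusted p = 6.21e-06, or adjusted p = 0.545 with an estimated correlation), led by COX7B (3.05 ± 0.61), COXFA4 (1.00 ± 0.26), NDUFB3 (0.76 ± 0.20) and NDUFV2 (0.77 ± 0.22), and was 0.21 (adjusted p = 0.0584) without scramble control 1 and 0.95 without scramble control 2. The homologous recombination list had a median of 0.44 (adjusted p = 3.96e-04, or adjusted p = 0.545 with an estimated correlation), led by RPA2 (0.84 ± 0.16), SEM1 (1.48 ± 0.37), RAD51AP1 (0.54 ± 0.16) and BRCA1 (0.98 ± 0.31), and was 0.002 (adjusted p = 0.421) without scramble control 1 and 0.81 without scramble control 2. The Fanconi anaemia and fork protection list, led by CLSPN (1.14 ± 0.30), USP1 (0.39 ± 0.13), TIMELESS (1.07 ± 0.45) and FANCF (0.48 ± 0.21), had a median of 0.29 (adjusted p = 0.042, or adjusted p = 0.609 with an estimated correlation). It was -0.002 (adjusted p = 0.844) without scramble control 1 and 0.53 without scramble control 2. Without CtBP2 knockdown arrays 1 and 2 it was 0.23 and 0.32 (adjusted p = 0.0677 and 0.0629). Glycolysis, at 0.22 (adjusted p = 0.0492, or adjusted p = 0.545 with an estimated correlation), was led by PFKFB3, which rose when adjusted over the list alone, PFKL (0.90 ± 0.29), PFKP (1.43 ± 0.48) and ALDOA (0.50 ± 0.19). It was -0.08 without scramble control 1 (adjusted p = 0.654) and 0.56 without scramble control 2. It lost its call, with medians from 0.17 to 0.23, without CtBP1 knockdown array 2 or 3 (adjusted p = 0.0509 and 0.076) and CtBP2 knockdown array 1 or 2 (adjusted p = 0.0592 and 0.0849).

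The list of inflammatory cytokines and NF-kB targets had a median of 0.55 (adjusted p = 5.81e-04, or adjusted p = 0.545 with an estimated correlation), with 20 of 25 genes higher. Between the controls it differed by 0.51 (scramble control 1 minus 2), above random lists matched on mean level (percentile 100). NFKB1, IL32 (2.29 ± 0.50) and IL1B (3.08 ± 0.71) rose when adjusted over the list alone, and IL6 differed by 3.04 ± 0.79. NFKB1 passed without each array in turn. IL32 and IL1B did not without scramble control 2 (adjusted p = 0.128 for both), CtBP1 knockdown array 3 (0.0624 for both) or CtBP2 knockdown array 1 (0.261 for both), nor did IL1B without CtBP1 knockdown array 1 (0.0914). The list's median was 0.76 without scramble control 1, 0.23 without CtBP2 knockdown array 1 and 0.35 without scramble control 2, where it was not called (adjusted p = 0.858). The anti-apoptotic list had a median of 0.40 (adjusted p = 0.0304, or adjusted p = 0.545 with an estimated correlation). Of its leading members CFLAR (0.49 ± 0.11), BIRC2 (0.64 ± 0.17) and BAG3 (1.22 ± 0.36) rose and BCL2 (-0.49 ± 0.11) fell when adjusted over the list alone. None of these 4 passed without CtBP1 knockdown array 3 or either CtBP2 knockdown array, at adjusted p from 0.0731 to 0.194. BIRC2 did not without scramble control 2 (0.0808), nor BAG3 without CtBP1 knockdown array 1 or 2 (0.0915 and 0.09), and BAG3 differed by 0.63 and 1.81 without scramble controls 1 and 2. The list of reported CtBP target genes had a median of 0.20 (adjusted p = 0.0399, or adjusted p = 0.545 with an estimated correlation), led by EPCAM (1.27 ± 0.32), IL6, BAX (0.79 ± 0.24) and CCND1 (0.99 ± 0.31), and no member passed. Without scramble control 2 these 2 lists lost their call (adjusted p = 0.238 and 0.404) while their medians were 0.38 and 0.35. Without CtBP2 knockdown array 1 they lost it at 0.21 and 0.15 (adjusted p = 0.0958 and 0.0705). The median of the CtBP targets was 0.10 without scramble control 1, where it was called. The hypoxia response list had a median of 0.18 (adjusted p = 0.0181, or adjusted p = 0.545 with an estimated correlation), which turned to -0.10 when the arrays were quantile-normalized again. Of its members 5 rose when adjusted over the list alone, among them BNIP3 (1.20 ± 0.17), P4HA2 (0.72 ± 0.12), ANGPTL4 (2.34 ± 0.41) and PLOD2 (0.79 ± 0.18). Of those 5, 4 passed without scramble control 1 or CtBP1 knockdown array 3, and 3 and 2 without CtBP2 knockdown arrays 1 and 2, BNIP3 and ANGPTL4 in each case. The median was 0.43 without scramble control 1, where the list was called, and 0.37 without scramble control 2, where it was not (adjusted p = 0.655).

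The leukocyte marker list, which marks cells not present in a pure culture, was the 1 list called lower, at -0.14 (adjusted p = 0.0492, or adjusted p = 0.545 with an estimated correlation). Its median turned to 0.000126 after renewed quantile normalization. It was led by ITGAX (-0.42 ± 0.15), MS4A1 (-0.35 ± 0.16), ITGAM (-0.32 ± 0.15) and LCP1 (-0.31 ± 0.20), and no member passed. It lost its call without scramble control 1 (median -0.05), CtBP1 knockdown array 3 (-0.14), or CtBP2 knockdown array 1 or 2 (-0.17 and -0.11), at adjusted p of 0.844, 0.0505, 0.0839 and 0.059. Without scramble control 2 its median was -0.27. Between the controls the leukocyte list differed like random lists matched on mean level (percentile 55.8), so its call may reflect the level of its genes. Over the 13 called lists, 17 of the 51 different leading members moved by over 1.5 times without a scramble array, and 0 changed sign. These members too were chosen by the smallest p on the same arrays, which makes a change of sign unlikely. The 16 lists not called had medians from -0.16 to 0.26 and adjusted p from 0.0684 to 0.958. Without scramble control 1 or without CtBP2 knockdown array 1, 8 lists were called. Of the 16, 3 were called without 1 array. They were cholesterol synthesis at -0.96 without scramble control 1 and 1.17 without scramble control 2, excision and mismatch repair at 0.47 without scramble control 2, and epithelial markers at 0.13 without CtBP2 knockdown array 2. With an estimated correlation these were not called either, at adjusted p from 0.337 to 0.6.

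**Figure D3:**
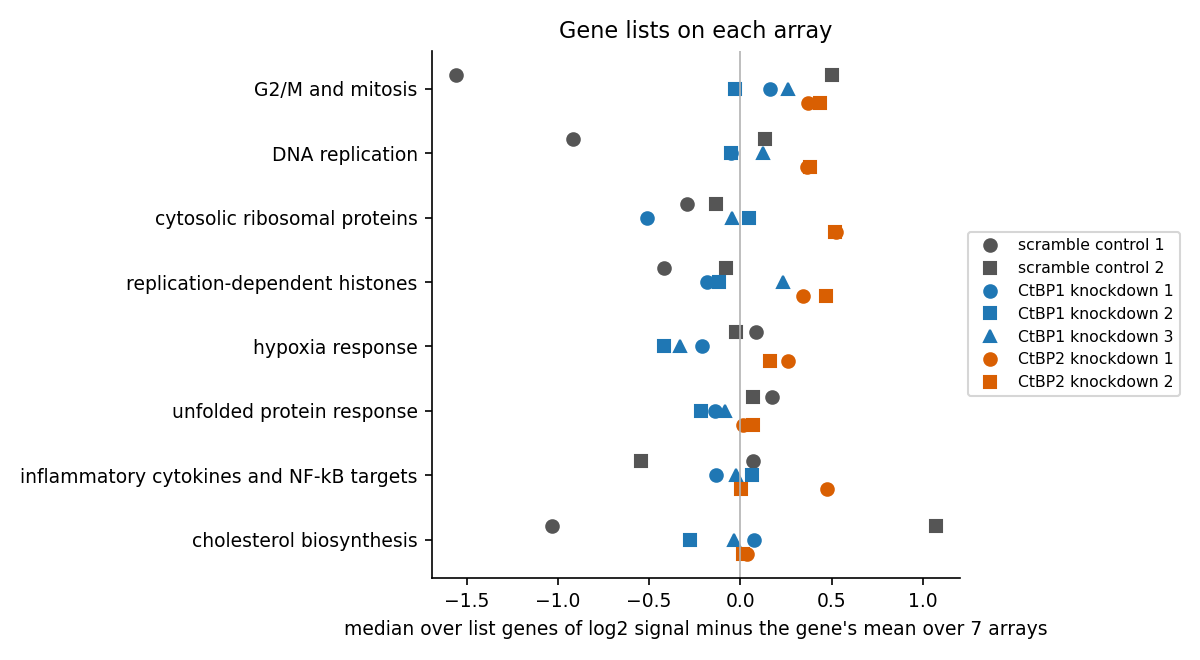
Median over the genes of 8 lists of the log2 signal minus the gene's mean over the 7 arrays (x axis, log2 units), with 1 symbol per array coloured by group. The G2/M list lies at -1.56 on scramble control 1 alone, the ribosomal protein list at 0.52 on both CtBP2 knockdown arrays, and the hypoxia list at -0.21, -0.42 and -0.33 on the arrays labelled CtBP1 knockdown.

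The direct comparison of the arrays labelled CtBP1 knockdown with the CtBP2 knockdown arrays addresses what the series was designed for, genes on which the knockdowns act differently. The differences use no control array, while their spread was taken from all 7 arrays. Higher on the arrays labelled CtBP1 knockdown were ITGB6, an integrin subunit of epithelial cells (2.07 ± 0.33, SE, 3 arrays against 2), the uroplakin UPK3B (1.93 ± 0.24), CTBP2 (1.85 ± 0.19), the urea transporter SLC14A2 (1.75 ± 0.28), TMEM92 (1.45 ± 0.13) and TCF7L2, a transcription factor of Wnt signalling (1.14 ± 0.13). Higher on the CtBP2 knockdown arrays were RNU4-1 (-2.69 ± 0.21), the histone gene H2BC3 (-2.57 ± 0.26), GPAM, which starts glycerolipid synthesis (-2.00 ± 0.22), the cytochrome c oxidase subunit COX7A2 (-1.77 ± 0.18), NT5E (-1.56 ± 0.14) and BNIP3, a hypoxia-induced mitophagy receptor (-1.42 ± 0.15). CTBP1 differed by -0.78 ± 0.39 with an adjusted p of 0.766. Its signals were 5.11, 6.13 and 6.13 on the arrays labelled CtBP1 knockdown and 6.81 and 6.32 on the CtBP2 knockdown arrays. Much of the difference thus came from CtBP1 knockdown array 1. The remaining genes named were TPD52L1 (1.32 ± 0.18), GNG11 (0.93 ± 0.11), FAM204A (0.90 ± 0.14) and the non-coding NBR2 (0.81 ± 0.12) on the higher side. On the lower side they were CCNQ (-1.26 ± 0.13), RCN1, a calcium-binding protein of the endoplasmic reticulum (-1.20 ± 0.13), NFKB1 (-1.20 ± 0.12) and the Cajal body RNA SCARNA9 (-1.05 ± 0.11).

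None of these genes passed: limma called 0 of 17958 at an adjusted p under 0.05, the smallest adjusted p was 0.129, and 1395 genes (441 higher, 954 lower) had an unadjusted p under 0.05. The unadjusted count was 2552 without either scramble array, and 671 and 727 without CtBP2 knockdown arrays 1 and 2. Separated groups were seen for 5739 genes (32.0%), where chance gives 20%. With array weights, which set both scramble arrays at 0.27 and the CtBP2 knockdown arrays at 2.66, 272 genes passed, 49 higher and 223 lower. In a group of 2 arrays the deviations mirror each other, so both arrays get the same weight. The weight of 0.27 thus cannot tell scramble control 2 from scramble control 1. After renewed quantile normalization 7 did.

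**Figure D4:**
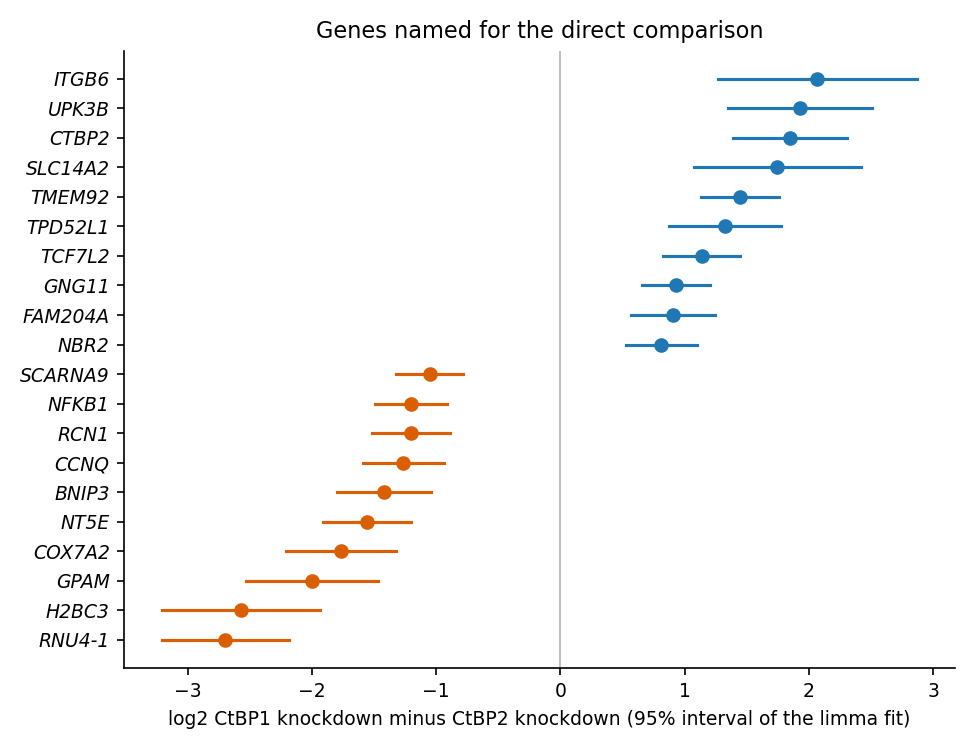
Log2 difference of the arrays labelled CtBP1 knockdown minus the CtBP2 knockdown arrays (x axis) for the 20 genes named for this comparison, with unadjusted 95% intervals from the limma fit. ITGB6 is highest at 2.07 and RNU4-1 lowest at -2.69, and none passed the adjusted threshold.

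Camera called 10 lists in the direct comparison, all of them lower on the arrays labelled CtBP1 knockdown, and none with an estimated correlation. Ribosomal protein genes had a median of -0.71 (adjusted p = 5.59e-20, or adjusted p = 0.293 with an estimated correlation), with 43 of 45 genes lower. Adjusted over the list alone, 16 members were lower past the threshold. They were led by RPS10 (-1.30 ± 0.16), RPL11 (-1.64 ± 0.22), RPL30 (-0.71 ± 0.12) and RPL7A (-0.54 ± 0.11). Of those 16, 15 passed without either scramble array, 6, 13 and 12 without CtBP1 knockdown arrays 1, 2 and 3, and 0 without either CtBP2 knockdown array. The hypoxia response list had a median of -0.44 (adjusted p = 1.54e-09, or adjusted p = 0.293 with an estimated correlation). Adjusted over the list alone, 8 of its 18 members were lower past the threshold. BNIP3, P4HA2 (-0.81 ± 0.11), the vasodilator peptide gene ADM (-1.68 ± 0.25) and STC2 (-0.86 ± 0.13) had the smallest p. Of those 8, all but P4HA1 passed without each array in turn. The histone list had a median of -0.47 (adjusted p = 8.28e-06, or adjusted p = 0.578 with an estimated correlation), with 5 of 22 members past the list threshold, led by H4C3 (-1.85 ± 0.26), H2BC8 (-1.15 ± 0.20), H4C1 (-0.78 ± 0.16) and H2AC4 (-1.48 ± 0.31). Of those 5, 4 passed without CtBP1 knockdown array 1 or 2, and 0 without either CtBP2 knockdown array. The DNA replication list, at -0.32 (adjusted p = 8.28e-06, or adjusted p = 0.768 with an estimated correlation), was led by ORC5 (-0.82 ± 0.14), its 1 member past the list threshold, GINS2 (-0.51 ± 0.16), RRM2 (-1.20 ± 0.39) and MCM6 (-0.71 ± 0.24). ORC5 did not pass without CtBP1 knockdown arrays 1, 2 and 3 (adjusted p = 0.208, 0.0933 and 0.182) or CtBP2 knockdown arrays 1 and 2 (adjusted p = 0.342 and 0.0618). The mitochondrial respiratory complex list, at -0.33 (adjusted p = 8.85e-05, or adjusted p = 0.768 with an estimated correlation), was led by SDHD (-0.94 ± 0.23), COX7B (-2.05 ± 0.55), COX6A1 (-0.91 ± 0.27) and NDUFV2 (-0.68 ± 0.20), and no member passed. Against scramble, the medians of these 5 lists in the order given were -0.01, -0.36, 0.26, 0.34 and 0.17 on the arrays labelled CtBP1 knockdown. On the CtBP2 knockdown arrays they were 0.78, 0.18, 0.69, 0.68 and 0.48. With all arrays, only the hypoxia list thus lay clearly below scramble on the arrays labelled CtBP1 knockdown. The others differed mainly through higher values on the CtBP2 knockdown arrays. The values against scramble depend on scramble control 1. With the preset correlation these 5 lists were called without each array in turn and under both renewed scalings.

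The 5 remaining lists were closer to the threshold, and apart from NFKB1 and IL1B no member passed when adjusted over the list alone. The anti-apoptotic list, at -0.24 (adjusted p = 0.0115, or adjusted p = 0.293 with an estimated correlation), was led by BIRC2 (-0.64 ± 0.15), MCL1 (-0.57 ± 0.16), BAG1 (-0.40 ± 0.16) and CFLAR (-0.24 ± 0.10). The reported CtBP target genes, at -0.13 (adjusted p = 0.0115, or adjusted p = 0.293 with an estimated correlation), were led by the keratin KRT18 (-0.50 ± 0.14), BRCA1 (-0.89 ± 0.29), CCND1 (-0.81 ± 0.28) and HIPK2 (0.53 ± 0.20). Both lost their call without CtBP2 knockdown array 1, at -0.18 and -0.12 (adjusted p = 0.133 and 0.0868). The unfolded protein response list, at -0.22 (adjusted p = 0.0298, or adjusted p = 0.293 with an estimated correlation), was led by VLDLR (-0.62 ± 0.13), SYVN1 (0.45 ± 0.12), HSP90B1 (-0.58 ± 0.18) and CREB3L2 (1.44 ± 0.48), and lost its call without CtBP1 knockdown array 1 or CtBP2 knockdown array 2, at -0.20 and -0.14 (adjusted p = 0.0956 and 0.168). The G2/M list, at -0.23 (adjusted p = 0.0389, or adjusted p = 0.802 with an estimated correlation), was led by CKS2 (-0.74 ± 0.19), BUB3 (-0.68 ± 0.23), CDC25A (-0.87 ± 0.34) and KIF2C (-0.94 ± 0.50). It lost its call without CtBP1 knockdown array 1 or 2, at -0.25 and -0.13 (adjusted p = 0.0956 and 0.108), and CtBP2 knockdown array 1 or 2, at -0.29 and -0.19 (adjusted p = 0.0604 and 0.162). The inflammatory list was at -0.16 (adjusted p = 0.0321, or adjusted p = 0.802 with an estimated correlation). It was led by NFKB1, IL1B (-3.57 ± 0.65), CCL20 (-1.08 ± 0.33) and CCL2 (1.43 ± 0.55). NFKB1 and IL1B were lower past the threshold adjusted over the list alone. IL1B did not pass without CtBP1 knockdown array 1 or 3 or CtBP2 knockdown array 1 (adjusted p = 0.0765, 0.0744 and 0.163). The list lost its call without either scramble array, at -0.16 (adjusted p = 0.0755 each), or CtBP1 knockdown array 1 or 3, at -0.11 and -0.19 (adjusted p = 0.251 and 0.0923). It was 0.03 without CtBP2 knockdown array 1 (adjusted p = 0.517), and was called at -0.43 without CtBP2 knockdown array 2 and at -0.25 without CtBP1 knockdown array 2. The 19 lists not called had medians from -0.17 to 0.12 and adjusted p from 0.0809 to 0.941. Without CtBP2 knockdown array 1, 6 lists were called. Epithelial markers were called at -0.07 without CtBP2 knockdown array 2 (adjusted p = 0.0355, or adjusted p = 0.523 with an estimated correlation).

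The effects of the knockdowns were also set against each other. The log2 differences from scramble correlated at 0.662 over all genes. Simulated unchanged groups that shared simulated controls gave 0.876 ± 0.003 (mean and SD of 100 simulated data sets). These simulations used each group's own spread and genes independent of each other. The covariance was 0.116 against a simulated 0.146. With limma 0 genes passed the threshold in both comparisons. At an unadjusted p under 0.05, 183 genes were higher in both and 163 lower in both, against 772 and 779 in the simulations and 37.1 and 10.3 for independent lists. The correlation was 0.537 without scramble control 1 and 0.877 without scramble control 2, where 2708 genes passed in both comparisons, and the covariance was 0.0685 and 0.439. The counts higher and lower in both were 197 and 433 without scramble control 1, and 2894 and 2472 without scramble control 2. They were 123 and 103 without CtBP1 knockdown array 2, 98 and 107 without array 3, and 89 and 52, and 116 and 63, without CtBP2 knockdown arrays 1 and 2. The controls were not split between the comparisons, since each would keep 1 control array, so part or all of the excess over independent lists may come from the shared controls. With all arrays the correlation, the covariance and both counts lay below the simulated values, and no simulation was made for fits without an array. The simulations gave a mean of 72.7 genes past the threshold in both comparisons, where the data gave 0. They do not resemble the data in this, so no conclusion is drawn from the values below them.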

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

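In 19 of the named genes every array labelled CtBP1 knockdown lay on one side of both scramble arrays and every CtBP2 knockdown array on the other. The difference between the knockdowns was tested directly with limma and passed in none of them, at adjusted p from 0.129 to 0.454. Values are log2 differences of the arrays labelled CtBP1 knockdown minus the CtBP2 knockdown arrays. CTBP2 itself is among them at 1.85, and so are TMEM92 (1.45), TCF7L2 (1.14), UPK3B (1.93), GNG11 (0.93), TPD52L1 (1.32), NBR2 (0.81), FAM204A (0.90), SLC14A2 (1.75), ITGB6 (2.07) and the ubiquitin ligase gene SYVN1 (0.45). In the opposite direction were the hypoxia genes ADM (-1.68), STC2 (-0.86), P4HA2 (-0.81) and KDM3A (-1.07), the small Cajal body RNA SCARNA9 (-1.05), the ribosomal protein gene RPL30 (-0.71), the lipoprotein receptor VLDLR (-0.62) and the keratin gene KRT18 (-0.50). Over all genes, 59 were above both controls on the arrays labelled CtBP1 knockdown and below them on the CtBP2 knockdown arrays, and 79 the opposite, where a random order of the arrays gives 85.5 of each, so the pattern was not more frequent than chance. TCF7L2, for example, differed from scramble by 0.66 on the arrays labelled CtBP1 knockdown and by -0.48 on the CtBP2 knockdown arrays, and ADM by -0.57 and 1.11.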

How the results depend on the processing

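Among the alternatives, the fit without genes of identical values and the estimated correlations without single arrays were added after the data were seen. The count of 1 gene for CtBP2 knockdown against scramble became 0 with every transcript cluster tested, with robust eBayes, with only the 2 groups compared, with array weights and with the replicate number as a block. In the fit with the block that call, the histone list for the arrays labelled CtBP1 knockdown (adjusted p = 0.244), the glycolysis and leukocyte lists for CtBP2 (0.0651 each) and the inflammatory list in the direct comparison (0.0801) were lost. That fit also sets aside CtBP1 knockdown array 3, the lone array of its number. Without that array and with no block the same calls were lost (adjusted p = 0.15, 0.349, 0.076, 0.0505 and 0.0923), so the losses are not shown to come from the block. Same-numbered arrays of different groups deviated from their group means with correlations from -0.35 to 0.10. In groups of 2 arrays the deviations mirror each other, so these values cannot decide whether the numbers pair the samples. In the direct comparison 0 genes became 7 after renewed quantile normalization and 272 with array weights. All 272 had an unadjusted p under 0.05 and the same sign in the unweighted fit. Both fits use the same arrays, so this is no separate support for the 272 calls.

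Lists called in the order of comparisons (labelled CtBP1, CtBP2, direct) were 6, 13 and 10. They became 0, 0 and 0 with an estimated correlation. After renewed quantile normalization 7 and 6 were called for CtBP2 and the direct comparison, 8 and 5 with the milder filter on dim genes, and for the 3 comparisons 3, 7 and 5 with the filter at the median level. For CtBP2 8 were called with the mean of all clusters, for the arrays labelled CtBP1 14 with every cluster, and in the direct comparison 6 without genes of identical values. Quantile normalization turned the CtBP2 hypoxia list to -0.0989 and the leukocyte list to 0.000126. Other CtBP2 calls lost were glycolysis (0.00344), Fanconi anaemia (0.0750), anti-apoptotic (0.168), CtBP targets (0.100) and homologous recombination (0.305). For the arrays labelled CtBP1 those lost were homologous recombination (0.108) and histones (0.238). In the direct comparison they were G2/M (-0.159), anti-apoptotic (-0.199), inflammatory (-0.124) and unfolded protein response (-0.126). Robust eBayes has no camera fit. The cause of these changes was not tested. With the milder filter, no list that lost its call had a median smaller in size than without the filter. For example, homologous recombination stayed at 0.27 for the arrays labelled CtBP1 knockdown, and CtBP2 glycolysis was 0.24 against 0.22.

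Leaving out each array gave 0 to 3262 genes and 6 to 13 lists for the arrays labelled CtBP1, 0 to 3952 genes and 8 to 13 lists for CtBP2, and 0 genes and 6 to 9 lists in the direct comparison. It gave CTBP1 differences of -0.585 to 0.0930, CTBP2 differences of -1.71 to -1.27, an effect correlation of 0.537 to 0.877 and 0 to 2708 genes called in both comparisons with scramble. For the arrays labelled CtBP1, list medians ran from -0.154 to 0.531 for homologous recombination, -0.0917 to 0.909 for DNA replication and -0.252 to 1.68 for G2/M. For CtBP2 they ran from -0.00229 to 0.531 for Fanconi anaemia, -0.0677 to 1.97 for G2/M and -0.0753 to 0.560 for glycolysis, and in the direct comparison from -0.426 to 0.0263 for the inflammatory list. The extremes came mostly from leaving out a scramble array. The signal over background was not measured here. Both filters on dim genes left the counts of genes past the threshold at 0, 1 and 0, while fewer lists were called.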

Other observations

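Several lists of cell identity and signalling were not called against scramble with all arrays. Epithelial markers had median log2 differences of 0.07 on the arrays labelled CtBP1 knockdown and 0.08 on the CtBP2 knockdown arrays against scramble, and mesenchymal markers -0.07 and -0.04, with adjusted p of 0.43, 0.0783, 0.779 and 0.905. The genes of CtBP's partner proteins had medians of 0.09 and -0.02 (adjusted p = 0.221 and 0.958), the p53 target genes -0.05 and 0.05 (adjusted p = 0.626 and 0.306), and the Wnt target genes -0.04 and -0.16 (adjusted p = 0.43 and 0.306). The interferon-stimulated genes had medians of 0.01 and -0.08 (adjusted p = 0.636 and 0.737), and the ERBB2 amplicon genes, which SKOV3 carries in extra copies, 0.29 and 0.26 (adjusted p = 0.0702 and 0.151). Fibroblast and endothelial markers, genes of cells not present in a pure culture, had medians of -0.09 and -0.10 (adjusted p = 0.0702 and 0.0783). Of these lists 3 were called without 1 array. They were epithelial markers for CtBP2 without CtBP2 knockdown array 2 (0.13), and for the arrays labelled CtBP1 the ERBB2 amplicon without CtBP1 knockdown array 2 (0.34) and fibroblast and endothelial markers without that array (-0.14) or scramble control 2 (-0.18). With an estimated correlation their adjusted p was 0.6, 0.586, 0.765 and 0.742. Among lists that were not called, the median had another sign than camera's direction for the reported CtBP targets, cholesterol synthesis and ribosomal proteins on the arrays labelled CtBP1 knockdown against scramble. The same held for CtBP's partners and mesenchymal markers on the CtBP2 knockdown arrays, and for mesenchymal markers, immediate-early genes and the ERBB2 amplicon in the direct comparison. The mean had another sign than both for the Wnt targets in all 3 comparisons and for mesenchymal markers on the arrays labelled CtBP1 knockdown.

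Cholesterol synthesis genes differed between the controls. The list median relative to each gene's mean was -1.03 on scramble control 1 and 1.07 on scramble control 2, with all 5 knockdown arrays between -0.28 and 0.07. HMGCS1 had log2 signals of 4.80 and 7.14 on these controls, SQLE 6.30 and 8.03, INSIG1 4.61 and 6.80, and IDI1 4.31 and 7.13 (genes chosen after their values were seen). The list was not called against both controls (adjusted p = 0.959 and 0.914). Its direction against scramble followed the control kept. Without scramble control 1 it was lower, at medians of -1.10 and -0.96 (adjusted p = 1.65e-13 and 6.22e-10, or adjusted p = 0.537 and 0.337 with an estimated correlation). It was higher without scramble control 2, at 1.00 and 1.17 (adjusted p = 8.21e-05 and 1.6e-04, or adjusted p = 0.363 and 0.498 with an estimated correlation).

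The tests in the paragraphs that follow were chosen after the result was seen, except the test of brightness for the ribosomal genes and that of the signal scale for CTBP1.

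The G2/M and mitosis list was lower on scramble control 1 than on scramble control 2 by a median of 2.09 log2 units, with MKI67 at 5.04 and 8.18 and PLK1 at 5.39 and 8.59 (chosen after their values were seen). A compressed signal scale is argued against as the whole cause, because the list lay at percentile 0 of 10000 random lists matched on mean level, whose central 95% ran from -0.98 to -0.48. A culture with fewer dividing cells stays open: 2 of 3 further proliferation lists lay below the 2.5 percentile (DNA replication at 0.03 and homologous recombination at 0.97, but Fanconi anaemia at 13.2). The design names no difference between the controls, and how the cultures were grown was not measured here.

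Ribosomal protein genes were lower on the arrays labelled CtBP1 knockdown than on the CtBP2 knockdown arrays (median -0.71, adjusted p = 5.59e-20, or adjusted p = 0.293 with an estimated correlation). A scale that moves all genes of that brightness alike is argued against, since the list lay at percentile 0 of 10000 matched random lists (central 95% from -0.24 to 0.06), and so is a single array, since without each knockdown array in turn the median closest to 0 was -0.553. An RNA preparation that kept more short RNAs in the CtBP2 samples stays open, with values on both sides: the 13 small nuclear RNA genes (median -1.32) and the 188 small nucleolar RNA genes (median -0.14) both lay at percentile 0 of matched random lists, and the labels and the design text name different extraction methods. Against scramble the small nuclear RNA genes had a median of 1.15 on the CtBP2 knockdown arrays (9 higher and 0 lower on both arrays than on both controls). The small nucleolar RNA genes, however, had -0.00698 (51 higher and 45 lower). The 180 microRNA genes had -0.13 (5 higher and 69 lower), and 0.06 between the knockdowns. The 525 long non-coding RNA genes, which are not short RNAs, had similar values of -0.18 (19 higher and 200 lower) and 0.07. The microRNA values therefore do not weigh on either side. An effect of CtBP2 also stays open, since each extraction method is not assigned to samples and was not tested apart from the groups. Transcript length was not checked, so the same question stays open for the histone and mitochondrial lists (medians -0.47 and -0.33 between the knockdowns).

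CTBP1 was not lower on 2 of the 3 arrays labelled CtBP1 knockdown than on both controls. The signal scale of scramble control 1 could contribute, since the difference of CTBP1 between the controls, -0.68, lay at percentile 56.6 of the 1702 genes of similar level, whose median was -0.77. Exchanged labels cannot be told apart from weak knockdown at the RNA level, since CTBP1 on scramble control 1 was -0.432 from the highest labelled array and genes of that level spread from -2.62 to 0.69 between the controls. Loss of CtBP1 protein with little change of its RNA, as the western blots named in the labels would detect, was not tested.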
